A study of Mus musculus with 6 samples.

How the data were processed

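RNA from nucleus accumbens (NAc) tissue of C57BL/6N mice was sequenced by the authors after conditioned place preference training with morphine or with saline. The series holds 6 samples, 3 per group, and its design text gives 6 mice per group. The labels do not say how the mice map to the samples, so the exact permutation p-values below measure the spread between samples, not mice. Limma also borrows variance from other genes, and camera compares a list with other genes. The p-values against random lists measure the spread between genes. Saline samples carry the replicate numbers 1, 2 and 3 and morphine samples 4, 5 and 6; no number is shared between the groups and no batch or pairing is given, so no block was fitted.

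The deposited file of each sample is a catalogue of alternative transcription and splicing events in transcripts assembled from that sample, with 20 type codes, an Ensembl gene ID, a chromosome, a start, an end and a pattern of splice positions. The column headed fpkm in these deposited files holds whole numbers between -24 and 0 in all 6 libraries, so it was not used as an expression value. The assembler, the event caller, the genome build and the read depth are not given in the sources used here. The boundaries of 65.3% of the distinct events are those of exons in the GENCODE M21 annotation of GRCm38, and coordinates below are read on that build. Because the depth behind a catalogue is unknown, no counting interval or detection limit was computed. An event that a catalogue does not list was not recorded there. That shows neither that its exons were not assembled nor that the transcript was absent.

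The measure was the number of distinct events per gene and library. The same assembled exon can count under several type codes, so event numbers are not numbers of exons or transcripts. Events were grouped into 5 classes: first exons, last exons, exon skipping, intron retention and alternative exon ends. The codes ending in OFF, which repeat a skipping or retention event for its partner transcript, were not counted. An event was the same in different libraries when its gene ID, type, strand and pattern of splice positions were the same. Symbols, biotypes and positions came from the annotation for 15833 of 15939 gene IDs, and 106 IDs had no match. A first or last exon was called annotated when its splice site was one of an annotated exon, and any other event when all its exons were annotated.

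The test fixed before the data were examined was limma on log2 expression values with a pseudocount of 0.5 and a minimum mean of 0.5. Expression values are not in the files used here, so the same limma model was fitted to log2 events per gene (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a mean-variance trend, Benjamini-Hochberg adjustment, 15040 genes with a mean of at least 0.5 events). Event counts are small whole numbers and 22.8% of the tested genes had the same count in all 6 libraries. For that reason each gene and the mean log2 events of each list were also compared with an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3, and genes were described as non-overlapping when every library of one group lay above every library of the other. The sums of each list were compared in the same way, which was chosen after seeing the data. Chance alone gives non-overlap for 10% of genes without ties, and ties lower this share. The exact test cannot reach an adjusted threshold of 0.05 with these samples.

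The fixed gene lists, 39 in all, were tested with camera (preset correlation 0.01, lists of at least 3 members, 37 lists), with camera under an estimated correlation, with camera on ranks and with fry. Named genes follow a rule fixed with the test, which asked for called and non-overlapping genes, but limma calls were not used in the choice. Named were the 10 non-overlapping genes with the largest log2 ratio in each direction and at most 2 predicted or unnamed models per direction. The 2 members of each list with the smallest exact permutation p were added, and 20 genes were named whatever their values. Ties were ordered by exact p, size, mean and alphabet. Cacng8, Kcnj3, Kif15, Stil, Senp3, Sstr2, Hdac5 and Acan were chosen after their values were seen. So were the other genes named for an event listed in 1 group alone, and Tmem191c, Phf20l1, Gtpbp6, Clk4 and Gapdh. Events per gene in a list were also compared with 10000 random lists matched on annotated exon number in 10 bins. This was a two-sided resampling test, with genes drawn with replacement.

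Alternatives planned in advance were pseudocounts of 0.1 and 1, no filter and a minimum mean of 1, quantile, median-of-ratios and equal-total scaling, limma without the trend, with robust eBayes and with sample weights, and leaving out each library. Median-of-ratios scaling gave a factor of 1 for every library and so changes nothing. Alternatives chosen after seeing the data changed which events were counted. Other splits of the 6 libraries into 3 and 3 were run for each count over all genes. Both tests were tested on simulated catalogues: of 100 genes given 4-fold more events, 94% were non-overlapping and limma called 35, and of 100 genes given 2-fold more events, 53% were non-overlapping and limma called 8. In the same simulation limma also called 88 unchanged genes, and it called 62 genes of 15210 where none had been changed. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Long non-coding RNA catalogues were not analysed here, and transcripts could not be compared by name because the files share no transcript IDs.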

Results

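Transcript structure was catalogued in the nucleus accumbens, a ventral striatal region that processes reward, from mice trained in conditioned place preference with saline or with morphine, an opioid receptor agonist. There were 3 libraries per group. The saline libraries listed 58007, 54641 and 57132 distinct events and the morphine libraries 57981, 56546 and 56416, in 14243, 14391 and 14791 genes and in 14263, 14284 and 14121 genes. The catalogues covered 15939 genes, of which 15711 were protein-coding and 36 were long intergenic non-coding RNAs, and 12938 genes were listed in all 6 libraries. Read depth is unknown, and all values below are numbers of distinct events per library, not expression levels.

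The comparison of morphine with saline addresses which transcript structures of the nucleus accumbens differ after morphine conditioning. Grik1, a kainate-type glutamate receptor subunit, had 15.7 ± 6.43 events in saline and 6.33 ± 1.15 in morphine (SD, n = 3 each; log2 ratio -1.19). Npas4, a transcription factor gene induced by neuronal activity, had 7.33 ± 2.52 events in saline and 13 ± 2.65 in morphine (log2 ratio 0.82), and the related early gene Nr4a3 had 2 events in each saline library and 3.33 ± 0.577 in morphine (log2 ratio 0.61). Foxp2, a transcription factor of striatal medium spiny neurons, had 6.33 ± 0.577 events in saline and 12 ± 4.36 in morphine (log2 ratio 0.82), and the postsynaptic scaffold gene Shank2 had 8 ± 2 and 13.7 ± 1.53 (log2 ratio 0.76). In each of these genes the groups did not overlap, and each had an exact permutation p of 0.1 (n = 3 per group), the smallest that 3 against 3 allows. Non-overlap held for 462 of 15040 tested genes, and other splits of the 6 libraries gave 363 to 469. It therefore does not show a morphine difference in any single gene. Of the 96 genes that limma called, 87 had identical counts within both groups, which none of these genes had. With first and last exons alone Npas4 and Shank2 overlapped, with exact-boundary types alone Npas4 did, and with partner rows counted Foxp2 did.

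**Figure D1:**
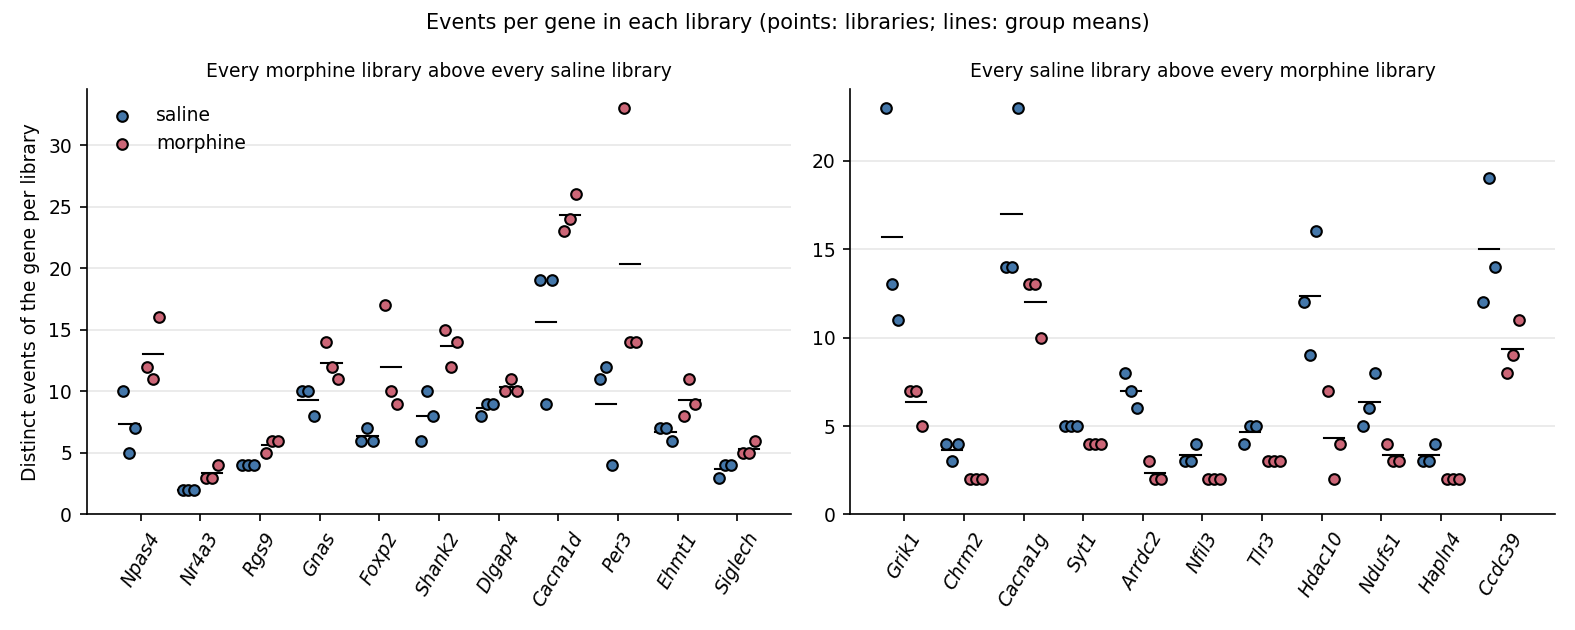
Distinct events (y axis, number per library) of 22 genes; points are libraries, blue for saline and red for morphine, and lines are group means of 3 libraries. In the left panel every morphine library lies above every saline library, as for Npas4 with 11 to 16 against 5 to 10, and in the right panel every saline library lies above every morphine library, as for Grik1 with 11 to 23 against 5 to 7.

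Among 27 tested immediate early genes, whose transcription follows neuronal activity, 2 had more events in every morphine library, Npas4 and Nr4a3, and 25 overlapped. Fos had 3.33 ± 1.53 events in saline and 2.33 ± 0.577 in morphine, Fosb 2 in each saline library and 2.33 ± 0.577 in morphine, Arc 2.33 ± 0.577 in saline and 2 in each morphine library, and Egr1 2 in all 6. The list summed to 77 ± 13 events in saline and 87.7 ± 5.51 in morphine (exact permutation p = 0.3 for the sum, adjusted p = 0.74 over 37 lists; 0.3 and 0.793 for mean log2 events, n = 3). Retained introns and alternative exon ends of Npas4 together numbered 7, 1 and 2 in saline and 8, 7 and 12 in morphine, which overlap at 7, and its other events numbered 3, 4 and 5 in saline and 4 in each morphine library. The same exon can count in both classes. In saline replicate 1 those from 4985755 to 4987450 and from 4985755 to 4988348 did so. In morphine replicate 4 those from 4987315 to 4987887 and from 4987315 to 4988348 did, and in replicate 5 that from 4985755 to 4987450. In morphine replicate 6 those from 4985755 to 4987887 and from 4988459 to 4988887 did. Such repeated counting thus fell on all 3 morphine libraries and on saline replicate 1, and how much it adds to the difference was not tested. Retention events of Npas4 alone overlapped too, with 5, 1 and 2 in saline and 5, 5 and 8 in morphine. With first and last exons alone Nr4a3 and Grik1 still did not overlap. One Npas4 retention event, which keeps both introns between positions 4987450 and 4988075 of chromosome 19 and matches the annotated exon from 4987315 to 4988348, was listed with exactly these boundaries in all 3 morphine libraries and in 0 saline libraries. A longer retention event, from 4987184 to 4988075, contains the same introns and was listed in saline libraries 1 and 3 and in 0 morphine libraries.

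**Figure D2:**
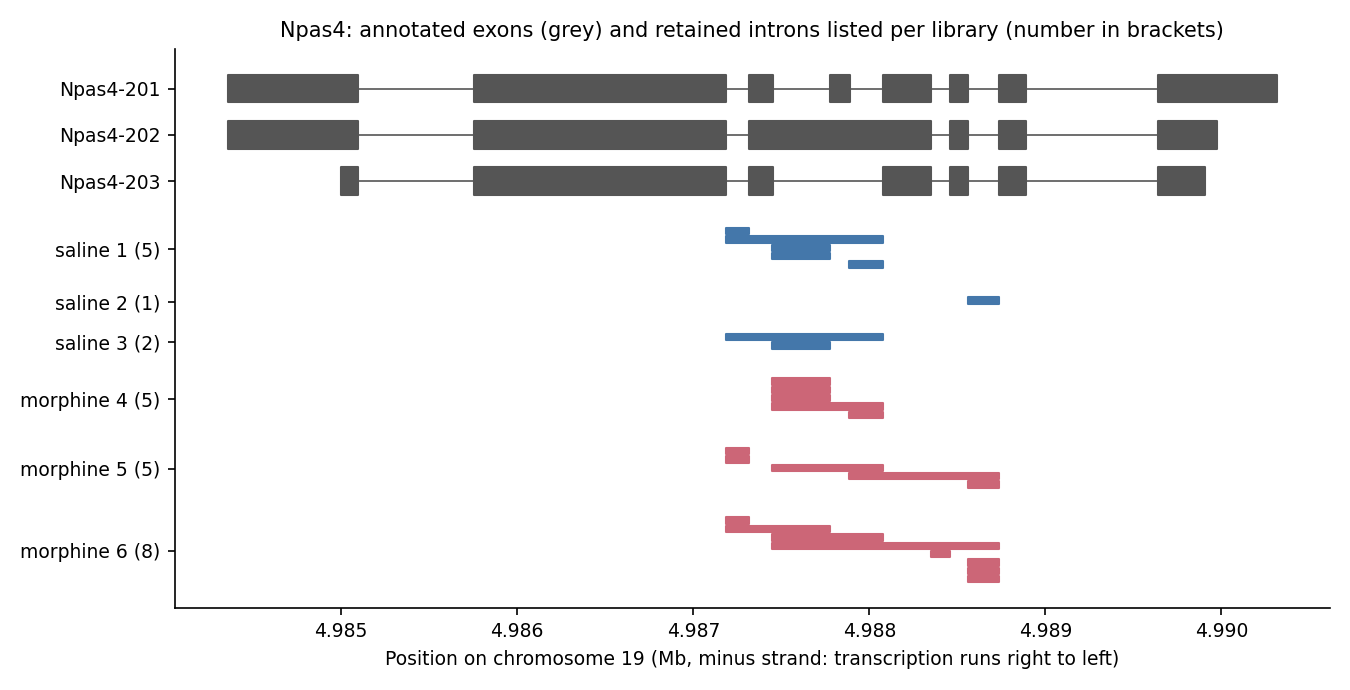
Map of Npas4 on chromosome 19 (x axis, position in Mb; the gene is on the minus strand) with annotated exons of 3 transcripts in grey and the intron retention events of each library below, blue for saline and red for morphine. Saline libraries list 5, 1 and 2 retention events and morphine libraries 5, 5 and 8.

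Medium spiny neurons, the projection neurons of the striatum, were represented by 18 general marker genes. The list summed to 84.3 ± 3.51 events in saline and 101 ± 3 in morphine, with 2 members above in every morphine library, Foxp2 and the striatal G protein regulator Rgs9, and 16 overlapping. Camera gave p = 0.0205 and an adjusted p of 0.728 for this list, adjusted p = 0.982 with an estimated correlation, and the exact permutation p was 0.1 for its mean log2 events (adjusted p = 0.74, n = 3) and 0.1 for its sum (adjusted p = 0.617). Markers of the D1 type, which make dynorphin, and of the D2 type, which make enkephalin, had 0 of 9 and 0 of 9 members apart. In the cAMP and DARPP-32 signalling list, through which dopamine and opioid receptors act, Gnas and Rgs9 were above in every morphine library and 25 of 27 members overlapped. Gnas, which encodes the stimulatory G protein subunit, had 9.33 ± 1.15 events in saline and 12.3 ± 1.53 in morphine, and Rgs9 had 4 in each saline library and 5.67 ± 0.577 in morphine. Both directions turned with first and last exons alone, to log2 ratios of -0.08 for Gnas and -0.40 for Rgs9, and Rgs9 overlapped with annotated events alone.

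All 8 opioid receptor and peptide genes overlapped between the groups: the enkephalin gene Penk and the dynorphin gene Pdyn had 2 events in all 6 libraries, the receptor genes Oprm1 and Oprd1 had 2.33 ± 0.577 and 2.67 ± 0.577 in saline and 2 and 2.33 ± 0.577 in morphine, and Oprk1 had 5 ± 1.73 in both groups. Pomc had 4 events in each saline library and 2.67 ± 1.15 in morphine, and Pnoc 3.67 ± 1.15 and 5. All 10 dopamine genes overlapped as well, with 3 events of the D1 receptor gene Drd1 in all 6 libraries, 3.67 ± 0.577 and 2.67 ± 0.577 events of the D2 receptor gene Drd2 in saline and morphine, 2.33 ± 0.577 and 2 of Drd3, and 2 and 2.67 ± 0.577 of Maoa, which degrades monoamines. The Drd2 exon at 49403194 to 49403280 of chromosome 9, whose inclusion separates the long from the short receptor, was listed as alternatively skipped in 5 of 6 libraries. Bdnf, a neurotrophin gene with several promoters, had 5 ± 1 events in saline and 3 ± 1 in morphine (exact permutation p = 0.2, n = 3).

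In the synaptic and channel lists single members stood apart in both directions. Among 24 glutamate receptor genes Grik1 alone did not overlap, and the AMPA receptor subunit gene Gria2 had 16 ± 5.29 events in saline and 8 ± 4 in morphine, with overlap. Of 27 postsynaptic genes, Shank2 and Dlgap4 were above in every morphine library, the latter with 8.67 ± 0.577 against 10.3 ± 0.577. The vesicle calcium sensor gene Syt1 had 5 events in each saline and 4 in each morphine library, while Syt7, with 18.7 ± 5.77 and 24.3 ± 3.51, overlapped. The L-type calcium channel gene Cacna1d had 15.7 ± 5.77 events in saline and 24.3 ± 1.53 in morphine, while the T-type gene Cacna1g had 17 ± 5.2 and 12 ± 1.73 and the G protein-gated potassium channel gene Kcnj3 had 4 in each saline and 3 in each morphine library. The muscarinic receptor gene Chrm2 had 3.67 ± 0.577 and 2. With annotated events alone Dlgap4, Syt1, Cacna1d, Cacna1g and Chrm2 overlapped, and with first and last exons alone Kcnj3 did. All 20 GABA genes overlapped, with 4.67 ± 2.08 and 3 events of Gabrg3 and 3 and 4.33 ± 1.15 of Gabra2.

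Chromatin, clock and stress-response lists held a few non-overlapping genes. Hdac10, a histone deacetylase family gene, had 12.3 ± 3.51 events in saline and 4.33 ± 2.52 in morphine (log2 ratio -1.51), and the histone methyltransferase gene Ehmt1 had 6.67 ± 0.577 and 9.33 ± 1.53. Per3, a clock gene, had 9 ± 4.36 and 20.3 ± 11 events, of which morphine replicate 4 alone held 33, and the clock repressor gene Nfil3 had 3.33 ± 0.577 and 2. Arrdc2, from the glucocorticoid response list, had 7 ± 1 and 2.33 ± 0.577 events (log2 ratio -1.41), while Sgk1, with 4.33 ± 0.577 and 4, and Wscd1, with 5 and 4.33 ± 0.577, overlapped and Fkbp5 had 2 in all 6 libraries. Ndufs1, a complex I subunit gene, had 6.33 ± 1.53 and 3.33 ± 0.577, and the other 40 oxidative phosphorylation genes overlapped. The innate immune receptor gene Tlr3 had 4.67 ± 0.577 and 3, but its log2 ratio was 0.16 without intron retention and alternative exon ends and 0 with first and last exons alone. The other 22 genes of its list overlapped, and the list summed to 46.3 ± 2.89 events in saline and 50.7 ± 1.15 in morphine, opposite to Tlr3. With annotated events alone Arrdc2, Hdac10, Ehmt1, Per3 and Nfil3 overlapped between the groups, and with first and last exons alone Ndufs1 did.

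Among cell type markers only single genes did not overlap. The ciliary gene Ccdc39, a marker of the ependyma that lines the ventricles, had 15 ± 3.61 events in saline and 9.33 ± 1.53 in morphine, within an ependymal list that summed to 40.7 ± 3.06 and 32 ± 2 events. The exact permutation p of this list was 0.1 for the sum, in which the groups did not overlap (adjusted p = 0.617), and 0.2 for mean log2 events (adjusted p = 0.74, n = 3). Tmem72, a choroid plexus marker, had 2 events in each saline library and was listed at 0 in morphine, whereas the choroid plexus gene Ttr had 2 in all 6. Aqp1 had 0 in each saline library and 2, 2 and 0 in morphine, with overlap. The smooth muscle actin gene Acta2 had 3 events in each saline and 2 in each morphine library. Siglech, a microglial lectin gene, had 3.67 ± 0.577 and 5.33 ± 0.577. Hapln4, a link protein gene of perineuronal nets, had 3.33 ± 0.577 and 2, while the matrix gene Tnr, with 6.67 ± 0.577 and 3.67 ± 2.08, overlapped (exact permutation p = 0.2, n = 3). Prox1, from the glutamatergic neuron list, had 3.33 ± 0.577 and 2. With annotated events alone Ccdc39 and Prox1 overlapped, and with first and last exons alone Siglech did. None of the 16 astrocyte, 18 myelin or 14 endothelial markers and none of the 52 ribosomal protein genes stood apart, and the myelin gene Mbp had 9.33 ± 1.15 events in both groups.

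At the level of single events, 413 were listed in all 3 morphine and 0 saline libraries and 444 in all 3 saline and 0 morphine libraries, in 652 genes. Other splits of the 6 libraries into 3 and 3 gave 699 to 851 such events, against 857 here, and so few splits cannot reach a share under 0.05. Simulated catalogues with no change gave 1016 to 1172. They redraw each event at its observed share, so an event found in 1 library can be redrawn in several. Their range is therefore no reference for this count. Cacng8, which encodes an auxiliary subunit of AMPA receptors, was listed with a first exon ending at 3394504 of chromosome 7 in every saline library and with an upstream first exon ending at 3391365, together with skipping of the coding exon from 3411175 to 3411258, in every morphine library. The skipping event starts from the splice site at 3394504, so this site was assembled in all 3 morphine libraries too. With first and last exons alone Cacng8 overlapped. The somatostatin receptor gene Sstr2 was listed with its last exon beginning at 113624167 of chromosome 11 in saline and at 113625589 in morphine. The saline exon was listed as far as 113626028, so the morphine exon begins inside it. Rgs9 had a last exon beginning at 109258699 of chromosome 11, on the minus strand, in the saline libraries alone. Its morphine libraries alone listed 2 alternative exon ends, from 109250027 to 109250056 and from 109250027 to 109258699, so the boundary at 109258699 was assembled in both groups. The deacetylase gene Hdac5, which had 9.33 ± 3.79 events in saline and 14 ± 6 in morphine, had a first exon ending at 102218687 of chromosome 11 in saline alone. Its morphine libraries alone listed alternative exon ends, among them those from 102218416 to 102218953 and from 102218416 to 102219281. These span that first exon, so the stretch was assembled in both groups. Gnas had a retained intron from 174328131 to 174328367 of chromosome 2 in morphine alone. The perineuronal net gene Acan had an annotated first exon ending at 79053608 of chromosome 7 in saline alone. The fixed lists held 52 such events in 38 of their 692 listed genes, and 0 of these were in opioid or dopamine genes.

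**Figure D3:**
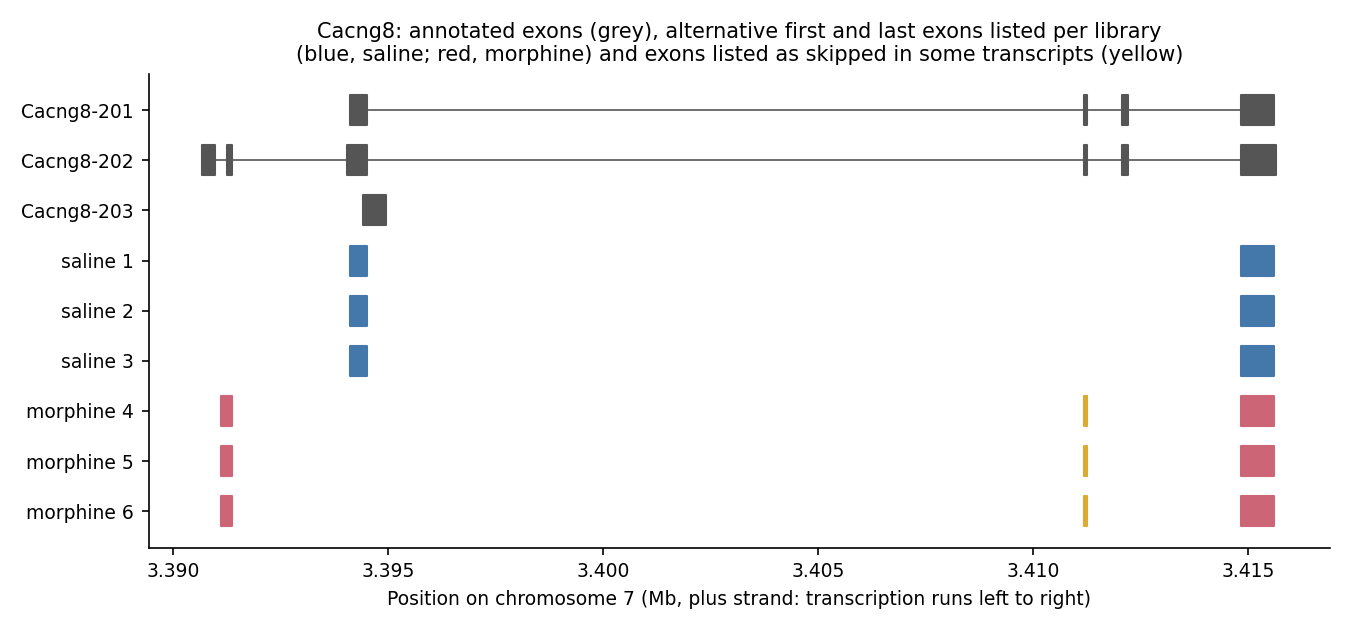
Map of Cacng8 on chromosome 7 (x axis, position in Mb; the gene is on the plus strand) with annotated exons of 3 transcripts in grey, alternative first and last exons of each library in blue for saline and red for morphine, and a skipped exon in yellow. The 3 saline libraries list the first exon ending at 3394504 and the 3 morphine libraries the one ending at 3391365 and the skipped exon.

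Whole genes listed in 1 group alone numbered 44, with 32 in saline and 12 in morphine. The saline genes included Mmp23, a membrane metalloproteinase gene (2.67 ± 0.577 events), C1qtnf3 (2.33 ± 0.577 events), the adenosine A3 receptor gene Adora3, the cannabinoid CB2 receptor gene Cnr2, the mitotic checkpoint kinase gene Bub1, Cdk15, the ciliary gene Cfap58, Ect2l, the translation initiation factor gene Eif4a1 and Fxyd3, of which the last 8 had 2 events in each saline library; all 10 were listed at 0 in morphine. The morphine genes included CK137956, Dqx1, Fcrl1, Filip1l, Gpr182, Pcdhb11, Sebox, the homeobox gene Six2, the erythrocyte anion exchanger gene Slc4a1 and the nuclear body gene Sp110, each with 2 events in every morphine library and listed at 0 in saline. The last-exon site of Eif4a1, at 69667617 of chromosome 11, was listed under the adjacent gene Senp3 in all 3 morphine libraries and in 1 saline library, and 2 events of Pcdhb11, 1 of a cluster of similar protocadherin genes, were listed under Pcdhb10 in 2 saline libraries, so that both listings are uncertain. A symbol of a predicted model or a bare gene ID belonged to 624 tested genes, 10 of them non-overlapping, among them 3100002H09Rik with 2.67 ± 2.52 events in saline and 9 ± 2 in morphine and 3830408C21Rik and 4930550C14Rik with 2 events in each saline library and 0 in morphine. With annotated events alone C1qtnf3, Sp110, Pcdhb11 and 3100002H09Rik overlapped. Malat1 and Meg3 were listed in 0 libraries. The housekeeping gene Gapdh was listed in saline replicates 2 and 3 and morphine replicate 4 alone, so an unlisted gene need not be a silent one.

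Totals of every event class, and of genes listed, differed between the groups by less than the SD of the saline libraries. Intron retention events numbered 7425, 5074 and 5010 in saline and 7523, 6361 and 7018 in morphine, or 5836 ± 1376 against 6967 ± 583 (ratio 1.19; exact permutation p = 0.3, adjusted p = 0.7 over 7 comparisons, n = 3). Exon skipping numbered 6227 ± 391 in saline and 5926 ± 19.3 in morphine (exact permutation p = 0.2, n = 3), first exons 21939 ± 675 and 21591 ± 307, last exons 16898 ± 238 and 16687 ± 186, and alternative exon ends 5692 ± 332 and 5809 ± 166, with exact permutation p-values of 0.6, 0.4 and 0.7 (n = 3). Genes listed numbered 14475 ± 283 and 14223 ± 88.7 (exact permutation p = 0.3, n = 3). Any library pair shared 47.7% of its events on average within a group and 47.5% between groups. Of 128790 events, 26901 were in all 6 libraries and 65299 in 1 library, and of 24972 intron retention events only 1.51% were in all 6.

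**Figure D4:**
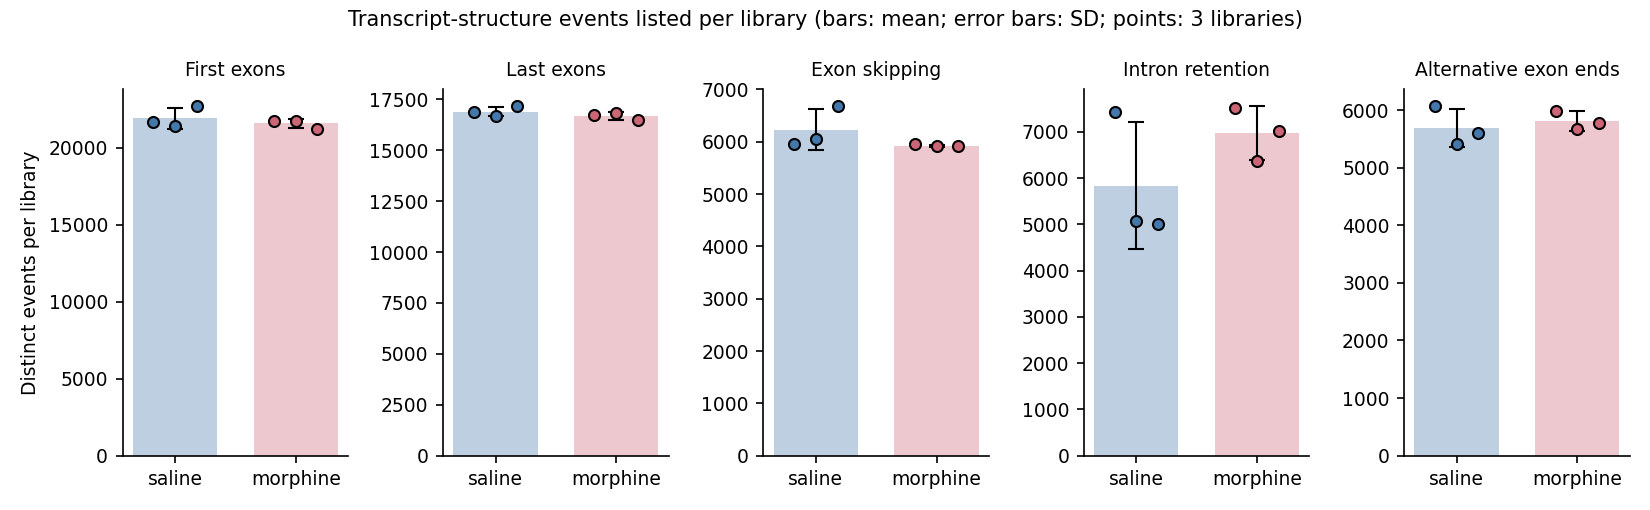
Distinct events per library (y axis, number) in 5 classes for saline (blue) and morphine (red); bars are means, error bars SD and points the 3 libraries. In intron retention saline replicate 1, with 7425, lies among the morphine libraries, and the other saline libraries lie at 5074 and 5010.

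Across 15040 tested genes, 462 were non-overlapping, 247 with morphine above and 215 with saline above, which is 3.07% of the tested genes. The larger share turned to saline with quantile normalization, with 225 and 233, and with first and last exons alone, with 114 and 142. Chance gives 10% only without ties. The 20 simulated catalogues with no change, which hold ties and draw each event independently, gave 385 to 485 such genes. They also gave 1016 to 1172 events listed in one group only, against 857 in the data. That excess arises at least in part because an event found in 1 library can be redrawn in several. The draws thus do not reproduce these catalogues in that respect, and their range for genes is only a rough reference. After adjustment 0 genes passed the exact permutation test, which with 3 against 3 also gives 0 at an unadjusted p under 0.05. Limma called 96 genes at an adjusted p under 0.05, 30 with more and 66 with fewer events in morphine, and 480 at an unadjusted p under 0.05. Of the 96, 87 had identical counts within both groups, as did Cacng8, with 2 events in each saline and 3 in each morphine library, so that their p rests on the variance borrowed from other genes. Robust variance estimation left 44 calls, and leaving out any 1 of the 6 libraries gave 250 to 285, with 127 more and 126 fewer without morphine replicate 6. Camera called 0 of 37 lists at an adjusted p under 0.05, also with an estimated correlation and on ranks. At an unadjusted p under 0.05 it had 1 list, 0 with an estimated correlation and 1 on ranks, ependymal markers with p = 0.0456. Sums of 6 lists did not overlap (exact permutation p = 0.1 and adjusted p = 0.617 for each, n = 3). These were medium spiny neuron, striatal interneuron, cAMP signalling, circadian clock and Toll-like receptor lists with more events in morphine, and ependymal markers with fewer. Fry, which asks whether members move on balance one way without comparing them with other genes, called 7 lists: medium spiny neuron markers, cAMP signalling and blood markers with more events in morphine, and choroid plexus, pericyte and smooth muscle, potassium and calcium channel, and presynaptic genes with fewer. The median log2 ratio of every one of these 7 lists was 0. Blood markers summed to 28.3 ± 7.51 events in saline and 27.3 ± 5.77 in morphine, with the opposite sign to their test. Fry works on log2 events per gene, however, and on that scale the mean ratio of this list was 0.217, with the sign of the test. The sign of the sums was also opposite for presynaptic genes, with 132 ± 2.65 and 138 ± 27, and for channel genes, with 208.7 ± 23.6 and 209 ± 16.7. The mean log2 ratio was 0.017 for presynaptic genes, opposite to the test, and -0.0063 for channel genes, with its sign. Slc4a1, Tmem72, Acta2, Kcnj3 and Syt1, from the blood, choroid plexus, pericyte and smooth muscle, channel and presynaptic lists, each had identical counts within both groups. How far the fry calls rest on such genes was not tested.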

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

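The alternatives that changed which events were counted were chosen after seeing the data, as were the class totals and the counts of events and genes listed in one group only, with all their alternatives, and all comparisons with other splits except that of the fry lists. The limma count of 96 genes stayed between 80 and 97 under other pseudocounts, filters, scalings, sample weights and no trend, fell to 44 with robust eBayes, and was 250 to 285 without any 1 library. Camera lists stayed at 0 in all its alternatives, and fry gave 7; the exact test called 0 lists on mean log2 events and on sums. Non-overlapping genes, a count chosen after seeing the data too, numbered 256 with first and last exons only and 961 to 1102 without any 1 library. More of them had saline above with quantile normalization (233 against 225), with first and last exons only (142 against 114), without retention and exon ends (170 against 141) and without any 1 saline library. Events listed in one group only numbered 569 with annotated events only, 536 without intron retention and alternative exon ends, 430 with first and last exons only and 2237 to 2388 without any 1 library, and genes listed in one group only 105 to 132. More one-group events were in morphine with partner rows (585 against 550), when matched by start and end (411 against 398) and without any 1 morphine library. The lower event counts follow from counting fewer events, and the higher ones from comparing 3 libraries with 2, where non-overlap is easier and the smallest exact p is 0.2. The cause of the robust eBayes count was not tested. The log2 ratios of class totals moved by less than 1 SD of the libraries where other events were counted or 1 library was left out, though that of intron retention went from 0.26 to 0.47 without replicate 1 and to 0.16 without replicate 2 or 3, and that of exon skipping from -0.07 to -0.02 without replicate 3. Those of first exons, alternative exon ends and all classes, near 0, changed sign in places. The totals themselves did not stay, as annotated retention events were 9.08% to 12.5% of all, and pseudocounts, scalings and limma settings were not run for them. Of 2057 alternative values of 121 named genes, 1892 lay within 1 SD of the reported value. Among 53 named genes without overlap, 35 stayed so with annotated events only, 45 with exact boundaries, 34 with first and last exons and 38 without retention and exon ends, and the sign turned in 0, 1, 2 and 2, among Rgs9, Gnas and Tlr3. The planned test per transcript was not run, since the files share no transcript IDs. Depth is unknown, so no limit of detection was set. With 10 splits of the 6 libraries no share under 0.05 is possible: limma calls were as many in 4 splits (96, highest other 105), non-overlapping genes in 2 (462, highest other 469), one-group events in 1 (857, highest other 851; another split was higher with annotated events only, 595 against 569, without retention and exon ends, 554 against 536, with partner rows, 1136 against 1135, and matched by start and end, 831 against 809), one-group genes in 6 (44, highest other 57), camera lists in 10 (0, highest other 0) and fry lists in 1 (7, highest other 6).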

Other observations

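All tests below except that of the mitotic genes were chosen only after the result was seen. Across both groups, 2 lists had fewer events per gene and library than random lists with matched exon numbers. Pericyte, smooth muscle and meningeal fibroblast markers had a mean of 2.32 against 4.39, and Toll-like receptor and cytokine genes 2.11 against 3.10 (resampling test, adjusted p = 0.0481 for each over 37 lists). Potassium and calcium channel genes, with 7.46 against 4.63, did not pass (permutation p = 0.0062, adjusted p = 0.0765). Genes are not independent replicates, and how well a gene is expressed was not matched.

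Some structures were shared by every library. Grin1, the obligatory NMDA receptor subunit gene, was listed with alternative skipping of its cassette exons at 25311343 to 25311405 and at 25294438 to 25294548 of chromosome 2 in all 6 libraries. Retained introns present in all 6 libraries lay in 308 genes, led by Tmem191c with 7, Phf20l1 with 5 and Gtpbp6 with 4, and included 2 in Clk4, a kinase gene of splicing factors. Of 39 translation factor genes, 38 were listed in every library, Eif4a1 being the exception. Of 25 mitotic and proliferation genes, 18, 19 and 23 were listed in the saline and 18, 19 and 21 in the morphine libraries.

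Intron retention totals were higher in the morphine mean, with saline replicate 1 among the morphine libraries. A thinner assembly of saline libraries 2 and 3 would lower genes listed along with retention, but the Pearson r between both was -0.769 over 6 libraries (exact permutation p = 0.0319, adjusted p = 0.0602 over 5 relations; Spearman rho -0.771, exact permutation p = 0.103, adjusted p = 0.257) and -0.112 without those 2 libraries, on which it rests. Retention and alternative exon ends were not related past adjustment either (Pearson r 0.915, exact permutation p = 0.0194, adjusted p = 0.0602; rho 0.886, exact permutation p = 0.0333, adjusted p = 0.167; r 0.931 without the same 2 libraries). These classes are not independent, since an exon that spans a retained intron can be listed in both, as for Grin1 in saline replicate 1. Unspliced RNA in a library may add to both classes, and that was not tested. An effect of morphine conditioning stays open, with an exact permutation p of 0.3 for 3 libraries against 3.

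Npas4 had more events in every morphine library, but its retention and exon-end events (7, 1 and 2 in saline, 8, 7 and 12 in morphine), its retention events alone and its exact-boundary types alone (7, 5 and 6, and 7, 7 and 9) each overlapped. A library-wide level of intron retention could produce it, since saline replicate 1, which has 7425 retention events in all, lists 7 Npas4 retention and exon-end events, as many as morphine replicate 5. Per 1000 such events of its library, Npas4 had 0.268 ± 0.223 in saline and 0.704 ± 0.203 in morphine (ratio 2.63, exact permutation p = 0.1, n = 3), and the smallest gap between the groups, 0.0631, is below the SD, so the library-wide level stays open. Exons counted in both classes enter these numbers in saline replicate 1 and in all 3 morphine libraries. Activity-dependent transcription would be expected to move related genes, but the other 26 immediate early genes summed to 69.7 ± 11 events in saline and 74.7 ± 5.51 in morphine (exact permutation p = 0.7, n = 3), and event numbers do not measure transcription. Both explanations cannot be told apart here, because 3 libraries per group and no expression values leave each test undecided.

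A gene listed in saline alone, Eif4a1, may have been assigned to a neighbour in morphine. Whether it was assembled into the neighbouring gene Senp3 stays open: its last-exon site was found under Senp3 in 3 morphine libraries, but also in saline replicate 2, which lists the same site under Eif4a1. Another last exon of Senp3, at 69673636, was listed in saline replicates 1 and 3 alone, so the morphine libraries list only the Eif4a1 site for Senp3. The first exon of Eif4a1 was at 69672279 in saline replicates 1 and 3 and at 69669078 in replicate 2. Of the 44 genes listed in one group only, 2 had an event under another gene where they were unlisted, Eif4a1 and Pcdhb11, which is listed in morphine alone, and 0 of Bub1, Kif15 and Stil did. These 3 genes act in cell division, and fewer dividing cells after morphine might remove them, but the number of 25 mitotic and proliferation genes listed was 20 ± 2.65 in saline and 19.3 ± 1.53 in morphine (exact permutation p = 0.9, n = 3). That leaves fewer dividing cells neither shown nor excluded, since low expression alone can leave a gene unassembled. Even the housekeeping gene Gapdh was unlisted in some libraries of both groups.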
